A study of Mus musculus with 18 samples.

How the data were processed

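Kidney RNA from 18 mice was measured on Affymetrix arrays, with 1 array per mouse. Per the labels, the 7-day mice were 6 controls and 6 Aprt KO mice, the 1-month mice were 3 controls and 3 Aprt KO mice, and each KO mouse had a control littermate of its own sex, which gives 9 pairs. The labels give 7 days and 1 month as the ages, while the series text speaks of newly born and adult mice; the ages of the labels are used here. Biotin-labelled cRNA was made from total RNA, per the labels' protocols. No array batch or scan date was used here, so a batch that coincides with age is not separable from age.

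The deposited values are intensity signals on a linear scale for 12488 probe sets, calculated with GCOS and MAS5 per the submitters' processing notes. Software versions and the scaling target are not given in the sources used here. In the deposited table the trimmed mean signal was close to 500 on each of the 18 arrays, with median signals from 160.1 to 216.4, the pattern a global scaling of each array leaves. Depth does not apply to arrays; their number, 3 to 6 in a group, limits the precision.

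The signals were used as deposited, without another normalization, and tested as log2(signal + 29), where 29 is the rounded 20th percentile of all values. A fold change on this scale understates the change of dim genes. Of the probe sets, 10833 had 1 gene symbol in the platform annotation, 396 had several, 1193 had none and 66 were control probe sets. No gene was named from a probe set with several symbols. Genes were kept where the mean signal reached the 40th percentile of all probe sets, a signal of 118.6, and each gene was represented by its brightest probe set, which left 5744 of 8251 genes. Spp1 and Havcr1, which the rule below also names, had no probe set with a single symbol and were not analysed here.

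A linear model was fitted to all 18 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with a term for each group and 1 sex term per age, leaving 12 residual degrees of freedom and a median of 5.7 prior degrees of freedom. The comparisons were Aprt KO against control at 7 days, the same at 1 month, the genotype-by-age interaction, and 1-month against 7-day controls. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all 5744 genes, and a gene was called at an adjusted p under 0.05. The 3 Aprt probe sets were adjusted among themselves. Figures were drawn with matplotlib 3.10.9.

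Gene lists were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the 29 lists tested in each comparison. The 30 lists cover tubular injury, cytokines and chemokines, myeloid cells, lymphocytes, antigen presentation, interferon response, complement and acute phase, extracellular matrix and fibrosis, proximal tubule, loop of Henle and distal convoluted tubule, collecting duct, podocytes, endothelium, renin-angiotensin and vasoactive genes, nephron progenitors and renal development, cell cycle, immediate early genes, p53 and growth arrest, unfolded protein and heat shock response, oxidative stress, hypoxia and glycolysis, oxidative phosphorylation, fatty acid oxidation and peroxisome, purine and polyamine metabolism, crystal binding, androgen and sex responsive genes, urothelium, blood, other tissues (fat, adrenal, muscle, liver, pancreas), and the neighbours of Aprt on its chromosome. Lymphocyte markers, with 4 measured members, were counted but not tested. Fry was also run. It tests whether the genes of a list move, on balance, to one side, and does not compare a list with other genes. Its adjusted p is given for genotype list calls that were lost with an estimated correlation.

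The named genes follow a fixed rule. For each genotype effect they are the 10 largest rises and the 10 largest falls among genes called and changed to the same side in every littermate pair, up to 4 members with the smallest p in the direction of each list past the camera threshold, and Aprt, Lcn2, Clu, Col1a1, Umod, Egf and Kap. For the interaction and for age they are the 5 largest rises and the 5 largest falls among called genes. Cyp24a1, Akr1b8, Igfbp3, Itih5, Ace, Dpep1 and Thy1, named as called members of their lists, and Lsp1 and the adrenal gene Cyp11a1 fall outside the rule and were chosen after their values were seen. Groups, comparisons, lists, this rule and most alternatives were fixed before the data were examined. The alternatives chosen after seeing the data were the removal of 4 arrays whose Aprt signal lay on the other group's side, with and without a litter term, and scores of adrenal and muscle genes as covariates, together with maturation estimates at each age in which no mouse or litter is shared.

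Littermates were checked for deviations in common. The deviations from the group means correlated at 0.239 to 0.673 within the 9 pairs, and 12 of the 18 arrays correlated best with their own littermate. The pairing comes from the labels, which name each mouse's littermate. The fit without the pair as a block is the main one, and the fit with it stands beside a result where it changes a call or moves a count by more than 1.5 times.

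The fits were tested on simulated data for 5744 genes with 200 changed genes. At 7 days 65.7% of the changed genes with a fold of 1.5 were recovered, and 100% at folds of 2 and 4, with 1 false call among 178. At 1 month these shares were 40.3% at a fold of 1.5, 82.1% at 2 and 97% at 4, with 0 false calls among 146. With the litter pair as a block there were 4 false calls among 192 at 7 days and 10 among 180 at 1 month. That fit also recovered more of the changed genes. At a fold of 1.5 it found 82.1% at 7 days and 64.2% at 1 month, and at a fold of 2 it found 92.5% at 1 month. Camera, tested on simulated 7-day data, called the list of 20 genes shifted by a fold of 1.5 and 0 of 20 unchanged lists. The simulated genes varied independently of one another, so this does not test camera on lists of correlated genes.

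Alternatives covered normalization, pseudocount, filter, the choice among probe sets, litter pair as a fixed or random block, sex terms, a block of mouse name series, the arrays in the fit, eBayes settings, array weights, and each array and each pair left out in turn. The correlation of genotype effects with the age change was compared with simulated unchanged KO groups against the same controls (100 draws).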

Results

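The series measured kidney RNA in mice labelled Aprt KO and in control littermates at 7 days and at 1 month of age. Aprt encodes adenine phosphoribosyltransferase, the enzyme that salvages adenine; without it adenine is oxidised to a poorly soluble product that crystallises in the kidney. There were 6 controls and 6 Aprt KO mice at 7 days and 3 of each at 1 month, in 9 littermate pairs of matched sex. Of the variance across the 18 arrays, 56.8% lay on the first principal component, which separated the ages. Xist and Eif2s3y matched the labelled sex in 18 of 18 arrays.

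Aprt itself gave a weak check of the labels. Its 3 probe sets were dim, at the 17.7, 20.9 and 35 percentiles of mean signal. The brightest read 115.5 ± 44.3 in the 7-day controls and 66.9 ± 34.1 in the 7-day arrays labelled Aprt KO (SD, n = 6). The log2 fold change was -0.58 (SE 0.23), with a limma adjusted p of 0.0672 over the 3 probe sets, and 0.0338 with the litter pair as a block. At 1 month the means were 107.1 ± 2.9 and 65.5 ± 18.4 (SD, n = 3), a log2 fold change of -0.54 (SE 0.33) with a limma adjusted p of 0.347. By array, the 7-day controls 1 to 6 read 66.3, 51.3, 148.2, 138, 141.2 and 148, and the arrays labelled 7-day Aprt KO 1 to 6 read 53.8, 55.4, 58.1, 135.4, 41.9 and 56.5. The 1-month controls read 109.5, 107.9 and 103.9, and the arrays labelled 1-month Aprt KO 86.5, 57.8 and 52.3. Against midpoints between group medians of 97.8 and 82.9, the Aprt signal goes against the label in 4 arrays, 7-day controls 1 and 2, the array labelled 7-day Aprt KO 4 and the array labelled 1-month Aprt KO 1. The last of these still reads below every 1-month control. The other probe sets changed by 0.10 and 0.13 at 7 days and by -0.12 and -0.07 at 1 month. Without 7-day control 1, 7-day control 2 or the array labelled 7-day Aprt KO 4, the 7-day Aprt difference passed the threshold (limma adjusted p 0.0155, 0.0149 and 0.0104). It also passed without pairs 1, 2 and 4 (0.0376, 0.0299 and 0.0232). These are the 7-day arrays on the other group's side of the midpoint, and their pairs. Leaving them out strengthens the difference by construction and does not check the labels. It is not known here whether any of these probes lies in a part of the gene that the KO allele alters. Every direction below therefore runs from arrays labelled control to arrays labelled Aprt KO.

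At 7 days the arrays labelled Aprt KO carried high levels of injury, acute phase and myeloid genes. Lcn2, an iron-sequestering lipocalin of injured tubules, rose from a signal of 280.3 ± 85.5 to 3321 ± 440.6 (SD, n = 6). Sprr2f, a small proline-rich protein of epithelia, rose from 70.8 ± 42.9 to 3297 ± 685. The largest log2 fold changes were those of Sprr2f (5.16, SE 0.26), the macrophage elastase Mmp12 (4.25, SE 0.38), Lcn2 (3.47, SE 0.17), the chemokine Ccl9 (2.82, SE 0.30) and the acute phase serpin Serpina3n (2.66, SE 0.17). Next came the interleukin-1 receptor antagonist Il1rn (2.55, SE 0.26), the monocyte chemokine Ccl2 (2.40, SE 0.31), Bcl3 of the NF-kB pathway (2.40, SE 0.14), lysozyme Lyz2 (2.38, SE 0.27) and the oncostatin M receptor Osmr (2.21, SE 0.20). All 10 were higher in 6 of 6 littermate pairs, a condition of being named, with limma adjusted p from 3.57e-10 to 6.55e-05. The falls were smaller. Klk1, a renal kallikrein, fell from a signal of 1398 ± 266 to 575 ± 236 (log2 fold change -1.32, SE 0.22), and Egf, made in the distal nephron, from 938 ± 270 to 400.4 ± 139 (-1.18, SE 0.21). The proteoglycan Ogn (-1.03), neuropeptide Npy (-0.99), the brush border protease Mep1b (-0.99), the mitochondrial adenylate kinase Ak4 (-0.88) and Klk1b5 (-0.87) fell too. So did Dmgdh of choline catabolism (-0.82), Aldh1a3 of retinoic acid synthesis (-0.82) and Col26a1 (-0.80). All 10 were lower in 6 of 6 pairs, again a condition of being named, with limma adjusted p from 1.49e-05 to 0.0287.

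**Figure D1:**
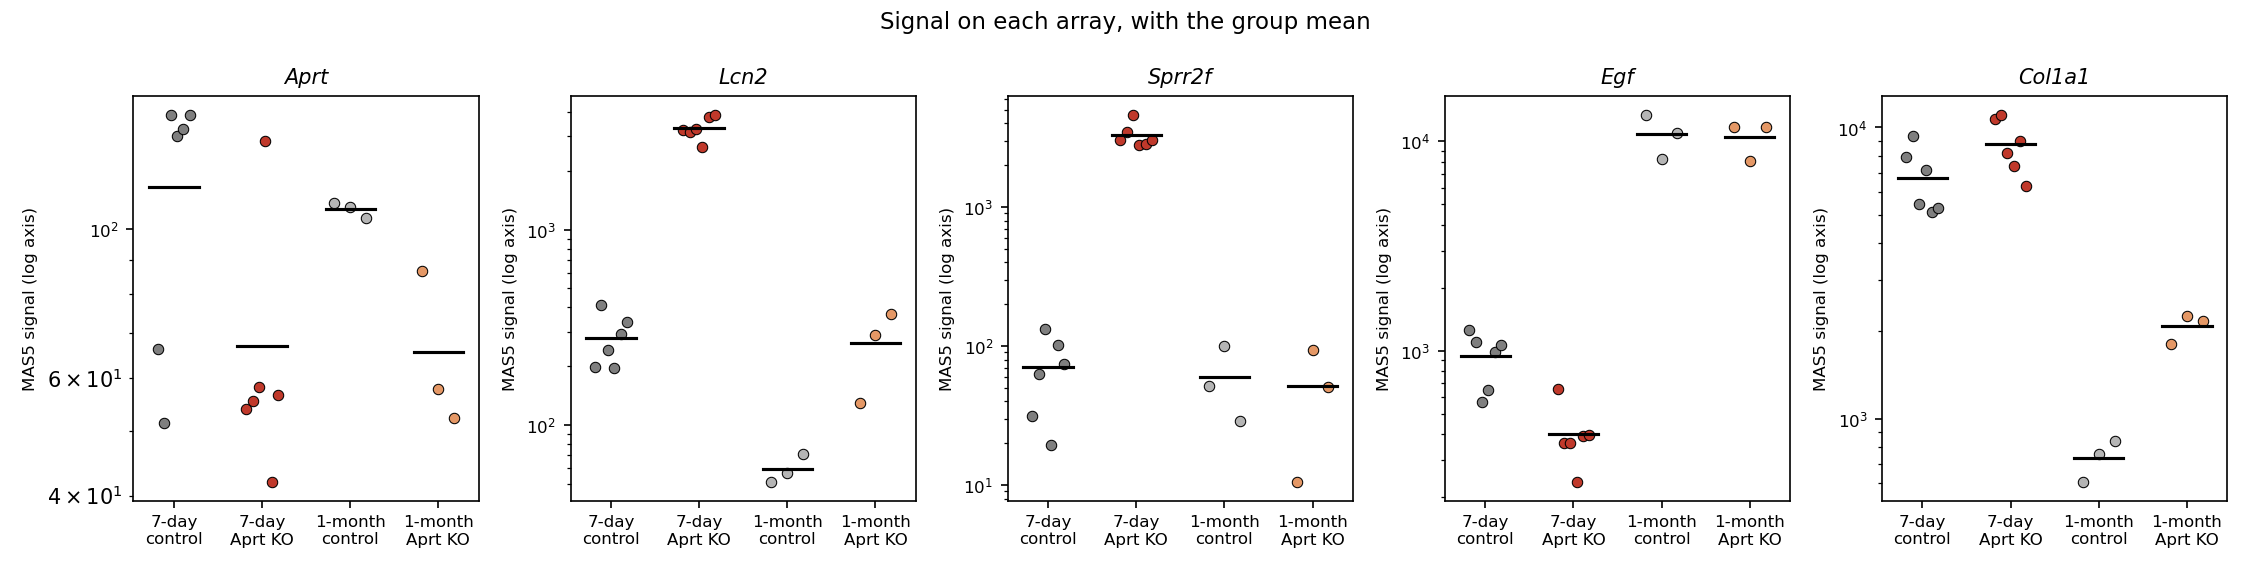
Signal of Aprt, Lcn2, Sprr2f, Egf and Col1a1 on each array (log axis), by labelled group, with a line at the group mean. Lcn2 spans 195.8 to 413.6 in 7-day controls and 2657 to 3864 in the 7-day arrays labelled Aprt KO, while the Aprt signals of those groups overlap.

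Of 18 measured tubular injury genes 11 rose, 0 fell and 7 did not pass, with 14 rising adjusted over the list alone. Keratin Krt19 (2.06, SE 0.15), the chaperone clusterin Clu (1.73, SE 0.14) and the adhesion molecule Icam1 (1.48, SE 0.17) were among them. The list rose with 17 of 18 members higher (median log2 fold change 0.68, camera adjusted p = 1.77e-27). Of 10 cytokine and chemokine genes 6 rose and 4 did not pass, Cx3cl1 among the rises (1.26, SE 0.13), and 6 rose and 1 fell adjusted over the list alone. With 9 of 10 members higher the list rose (median 1.02, camera adjusted p = 5.47e-13). Myeloid markers showed 17 of 22 rising, and 19 rising with 1 falling adjusted over the list alone. They included the lipopolysaccharide receptor Cd14 (1.74, SE 0.11), the complement subunit C1qa (1.49, SE 0.17) and lysosomal Cd68 (1.05, SE 0.13), and 21 of 22 were higher (median 0.79, camera adjusted p = 3.18e-33). Complement and acute phase genes rose in 9 of 15 cases, 11 adjusted over the list alone, led by Lcn2, Serpina3n and complement factor Cfi (2.005, SE 0.14). Of these 15 members 14 were higher (median 0.74, camera adjusted p = 1.07e-24).

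Immediate early genes rose in 12 of 27 cases, 16 adjusted over the list alone, among them Egr2 (1.93, SE 0.20), the cytokine signalling inhibitor Socs3 (1.78, SE 0.15), Fos (1.74, SE 0.21) and Ier3 (1.16, SE 0.20). Here 25 of 27 members were higher (median 0.46, camera adjusted p = 1.36e-21). Matrix genes rose in 7 of 43 cases, 15 adjusted over the list alone. They included Mgp, an inhibitor of calcification (1.32, SE 0.15), Tgfbi (1.20, SE 0.15), smooth muscle Tagln (0.84, SE 0.10) and Lgals1 (0.57, SE 0.12), with 38 of 43 members higher (median 0.28, camera adjusted p = 1.09e-14). Col1a1 read 0.39 (SE 0.16) at a limma adjusted p of 0.319, and 0.0104 with the litter pair as a block, higher in 6 of 6 pairs. These 6 lists held with an estimated correlation, though at a much larger camera adjusted p, from 0.00031 for cytokines to 0.0019 for immediate early genes. Antigen presentation genes rose in 2 of 19 cases, 4 adjusted over the list alone, namely the invariant chain Cd74 (1.28, SE 0.31) and the protease Ctss (1.95, SE 0.29), each higher in 5 of 6 pairs. As a list they rose with 18 of 19 higher (median 0.22, camera adjusted p = 9.95e-06, adjusted p = 0.327 with an estimated correlation). Of 17 crystal binding genes Mgp, Anxa1 (0.67) and S100a8 (1.06) rose, while Itih5, a hyaluronan-binding heavy chain picked after its value was seen, fell; adjusted over the list alone 3 rose and 1 fell. That list rose with 12 of 17 higher (median 0.13, camera adjusted p = 0.0091, adjusted p = 0.118 with an estimated correlation). By fry the crystal binding list passed (adjusted p = 0.012) and the antigen presentation list did not (0.194).

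**Figure D2:**
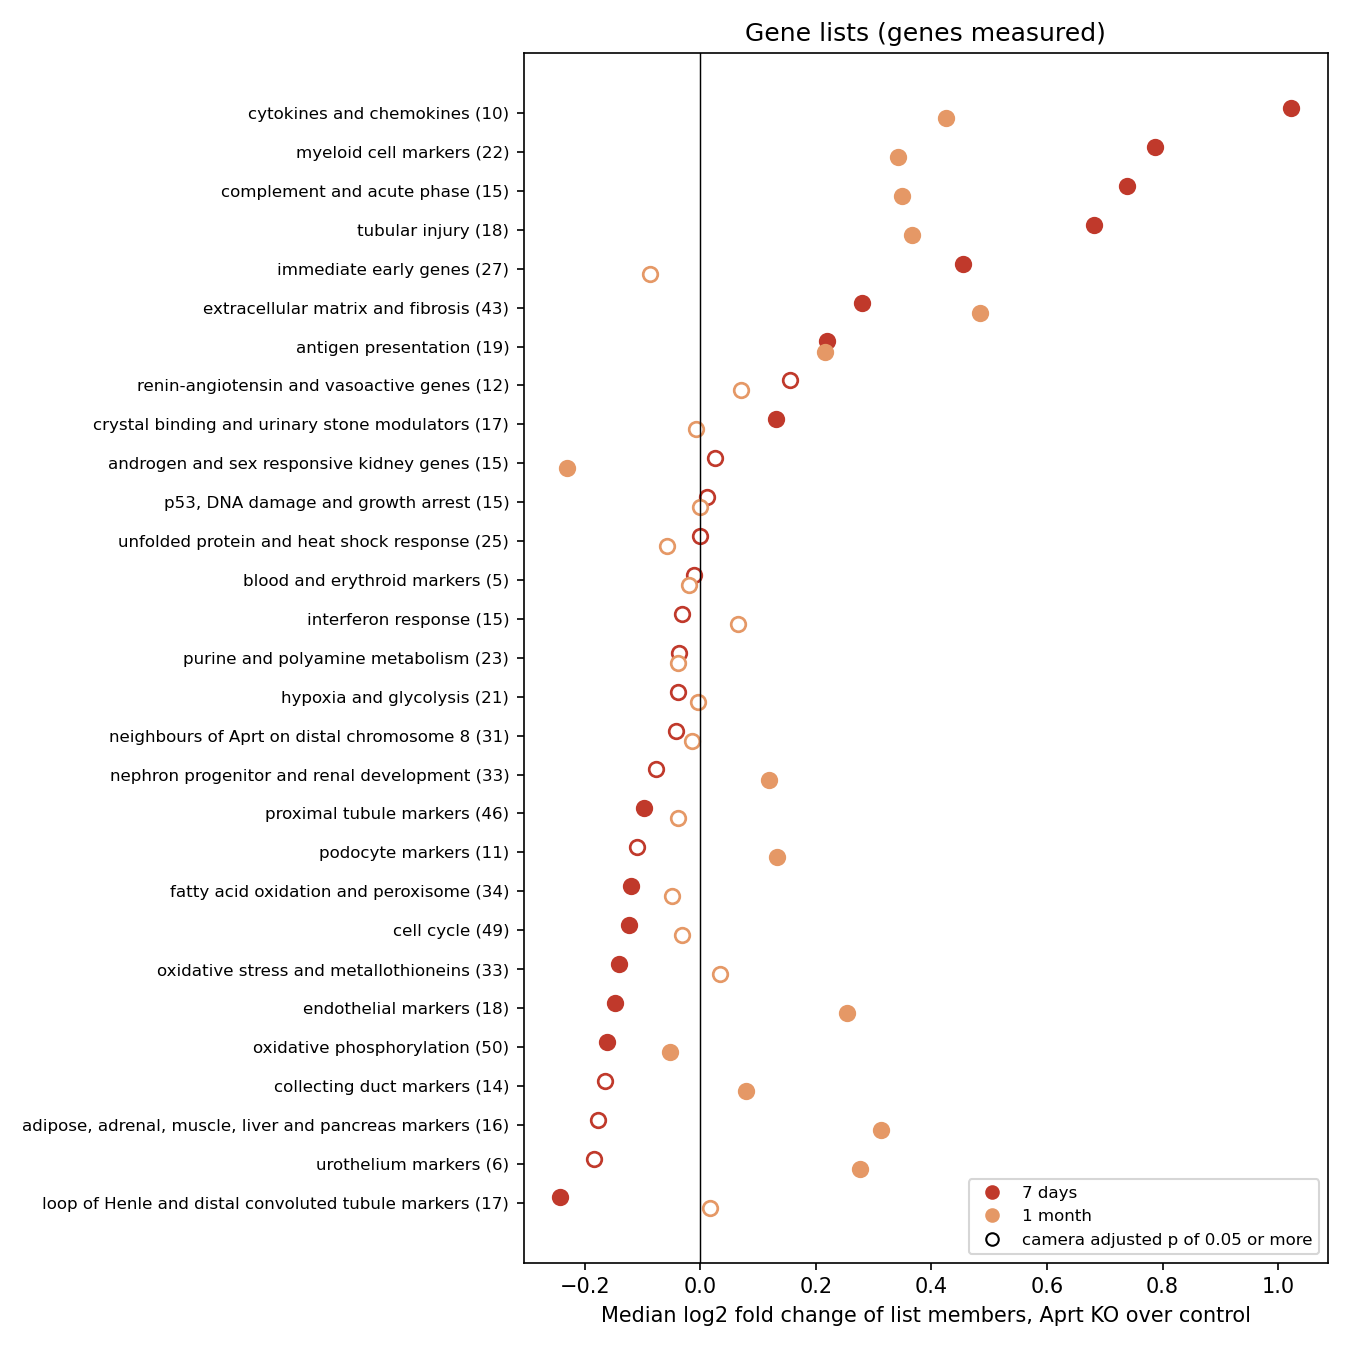
Median log2 fold change of the members of 29 gene lists in arrays labelled Aprt KO over control, at 7 days and 1 month; filled points have a camera adjusted p under 0.05. The cytokine list has the highest 7-day median at 1.02, and the matrix list the highest 1-month median at 0.48.

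The 7-day list calls toward lower levels covered tubule, energy, oxidative stress, cell cycle and endothelial genes, and none of them held with an estimated correlation. By fry the loop of Henle (adjusted p = 0.012) and endothelial (0.0473) lists passed. The others did not, with a fry adjusted p from 0.0734 to 0.194. Loop of Henle and distal tubule markers fell in 4 of 17 cases, 6 adjusted over the list alone. These were Egf, the monocarboxylate transporter Slc16a7 (-0.66), the calcium-binding S100g (-0.70) and the potassium channel Kcnj1 (-0.41). The list fell with 3 of 17 higher (median -0.24, camera adjusted p = 3.34e-06, adjusted p = 0.0944 with an estimated correlation). Umod, the major urinary glycoprotein of the thick limb, read 0.02 (SE 0.14). Among 46 proximal tubule markers Mep1b and Gsta2 (-0.74, SE 0.16) fell while Cyp24a1, the vitamin D hydroxylase, rose, and 2 rose and 4 fell adjusted over the list alone. The list fell with 13 of 46 higher (median -0.10, camera adjusted p = 0.00581, adjusted p = 0.387 with an estimated correlation). Kap, an androgen-regulated protein of the proximal tubule, read -0.34 (SE 0.26) at a limma adjusted p of 0.834, lower in 6 of 6 pairs. It passed in 1 of 48 alternatives, the litter pair as a fixed block (limma adjusted p = 0.00362), and not with the pair as a random block (0.175). Oxidative phosphorylation genes had 0 of 50 called by limma, 0 adjusted over the list alone, and 2 higher (median -0.16, camera adjusted p = 2.59e-06, adjusted p = 0.318 with an estimated correlation). Fatty acid oxidation had 0 of 34 called by limma, 0 adjusted over the list alone, and 1 higher (median -0.12, camera adjusted p = 0.00133, adjusted p = 0.276 with an estimated correlation). Among 33 oxidative stress genes Gsta2 and Gsta4 (-0.71) fell and Akr1b8 rose, with 1 rising and 3 falling adjusted over the list alone. That list fell with 10 of 33 higher (median -0.14, camera adjusted p = 0.0091, adjusted p = 0.177 with an estimated correlation). Ccnd1 (-0.36) was the only one of 49 cell cycle genes to fall, also adjusted over the list alone. The list fell with 8 of 49 higher (median -0.12, camera adjusted p = 0.00483, adjusted p = 0.387 with an estimated correlation). Endothelial markers fell as a list with 3 of 18 higher (median -0.15, camera adjusted p = 0.0411, adjusted p = 0.191 with an estimated correlation). Their only called member, the growth factor carrier Igfbp3, rose, also adjusted over the list alone.

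In all, limma called 185 of 5744 genes at 7 days, 146 higher and 39 lower, and 55 changed more than 2-fold. With the litter pair as a block 500 genes were called, 278 higher and 222 lower, which moved the higher share from 78.9% to 55.6%. The count was 110, 123 and 112 without pairs 1, 2 and 5, and 97 without the 4 arrays whose Aprt signal goes against the label. The 10 largest rises and Klk1 kept their calls in every alternative, though Lcn2 rose by 1.79 rather than 3.47 with the mean over its 2 probe sets. Kcnj1 lost its call in 28 of 48 alternatives, Gsta4 in 26, Ccnd1 in 22, Cd74 in 18, S100g in 15 and Aldh1a3 in 14, and Klk1b5 in 13 of 47.

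The other 7-day lists did not pass. Collecting duct markers had a median of -0.16 and a mean of 0.01 (camera adjusted p = 0.373, 4 of 14 higher), with 3 members called higher and 2 lower. Podocyte markers read -0.11 (0.154, 2 of 11 higher), nephron progenitor genes -0.08 (0.197, 12 of 33), urothelium -0.18 (0.187, 1 of 6) and other-tissue markers -0.18 (0.0877, 1 of 16) in median log2 fold change and camera adjusted p. Androgen responsive genes read 0.03 (0.264, 9 of 15), p53 and growth arrest genes 0.01 (0.0838, 9 of 15) and purine and polyamine genes -0.04 (0.986, 10 of 23). Interferon genes had a median of -0.03 with an upward test (0.847, 6 of 15), blood markers a median of -0.01 with an upward test (0.974, 2 of 5), and hypoxia genes a median of -0.04 and mean of 0.02 with a downward test (0.905, 8 of 21). Renin and vasoactive genes had a median of 0.16 and a mean of -0.05 with a downward test (0.974, 7 of 12), and Klk1 and Ace fell. Unfolded protein genes read 0.00 in median and -0.04 in mean (0.788, 13 of 25), and the chromosomal neighbours of Aprt -0.04 and 0.00 (0.91, 12 of 31), with Dpep1 called lower. All 4 measured lymphocyte markers were higher, and Thy1 rose.

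At 1 month the arrays labelled Aprt KO had higher extracellular matrix genes, with Lcn2 still raised. Col1a1, the main fibrillar collagen chain, rose from a signal of 732 ± 117 to 2076 ± 235 (SD, n = 3), a log2 fold change of 1.47 (SE 0.23). Lcn2 rose from 59.7 ± 10.4 to 262.8 ± 123 (1.62, SE 0.23), and each was higher in 3 of 3 pairs with a limma adjusted p of 0.00653. The largest rises also held Krt19 (1.26, SE 0.21), Col1a2 (1.102, SE 0.17, whose second probe set had the opposite sign), Col3a1 (1.08, SE 0.16) and calcium-binding S100a6 (1.07, SE 0.22). They were followed by Cfi (1.04, SE 0.20), the matricellular Smoc2 (0.98, SE 0.19) and Postn (0.96, SE 0.18), and Tcf21, a stromal and podocyte transcription factor (0.96, SE 0.17). All were higher in 3 of 3 pairs, as the naming rule requires, with limma adjusted p up to 0.0442. The only gene called lower was Aard, which fell from 97.8 ± 25.1 to 30.3 ± 5.57 (-1.08, SE 0.21, limma adjusted p = 0.0342, lower in 3 of 3 pairs). Its signal in those arrays was close to the pseudocount of 29, and over the alternatives the log2 fold change ranged from -1.64 with a pseudocount of 1 to -0.55 with a pseudocount at the 40th percentile, where it no longer passed.

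Of 43 matrix genes 6 rose at 1 month, Col1a1, Col1a2, Col3a1, Lum (0.90), Dcn (0.83) and Postn, and 16 adjusted over the list alone. With 39 of 43 higher the list rose (median 0.48, camera adjusted p = 1.87e-30). Tubular injury genes rose in 2 of 18 cases, Lcn2 and Krt19, and in 7 adjusted over the list alone, with 16 higher (median 0.37, camera adjusted p = 1.38e-12). Among complement genes Lcn2, Cfi and the inhibitor Serping1 (0.68, SE 0.14) rose, 3 of 15, the same adjusted over the list alone, with 13 higher (median 0.35, camera adjusted p = 1.85e-09). Cytokines had 0 of 10 called by limma, 3 adjusted over the list alone and 8 higher (median 0.43, camera adjusted p = 0.00196). Endothelial markers rose as a list with 0 of 18 called by limma, 0 adjusted over the list alone, and 13 higher (median 0.25, camera adjusted p = 0.00196). Androgen and sex responsive genes fell as a list with 0 of 15 called by limma, 1 falling adjusted over the list alone and 4 higher (median -0.23, camera adjusted p = 7.24e-05). Hsd17b11, a steroid dehydrogenase of that list, read -0.56 (limma adjusted p = 0.155, and 0.0326 with the litter pair as a block), lower in 3 of 3 pairs. These 6 lists held with an estimated correlation, though at a larger camera adjusted p, from 0.00018 for matrix genes to 0.0468 for endothelial markers.

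The remaining 1-month list calls were lost with an estimated correlation, and none of them passed by fry (adjusted p from 0.0987 to 0.86). Myeloid markers had 0 of 22 called by limma, 4 adjusted over the list alone and 17 higher, Lyz2 reading 1.19 (median 0.34, camera adjusted p = 1.62e-06, adjusted p = 0.123 with an estimated correlation). Antigen presentation had 0 of 19 called by limma, 0 adjusted over the list alone, and 17 higher (median 0.22, camera adjusted p = 0.0167, adjusted p = 0.728 with an estimated correlation). With the litter pair as a block that list no longer passed (camera adjusted p = 0.0549, 17 of 19 higher). Among 11 podocyte markers Tcf21 rose, 2 adjusted over the list alone, with 8 higher (median 0.13, camera adjusted p = 0.00459, adjusted p = 0.146 with an estimated correlation). Nephron progenitor genes had 0 of 33 called by limma, 1 adjusted over the list alone and 21 higher (median 0.12, camera adjusted p = 0.0311, adjusted p = 0.163 with an estimated correlation). Among 14 collecting duct markers Krt19 rose, 1 adjusted over the list alone, with 10 higher (median 0.08, camera adjusted p = 0.0329, adjusted p = 0.271 with an estimated correlation). Urothelium had 0 of 6 called by limma, 2 adjusted over the list alone and 4 higher, with Upk2 at 0.97 (median 0.28, camera adjusted p = 0.0182, adjusted p = 0.0816 with an estimated correlation). Oxidative phosphorylation fell with 0 of 50 called by limma, 0 adjusted over the list alone, and 10 higher (median -0.05, camera adjusted p = 0.049, adjusted p = 0.728 with an estimated correlation). Crystal binding genes had a median of -0.01, a mean of 0.13 and an upward test with 8 of 17 higher (camera adjusted p = 0.0791, and 0.0241 with the litter pair as a block).

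Markers of other tissues were also higher beside the 1-month matrix genes. Their list rose with 0 of 16 called by limma, 0 adjusted over the list alone, and 11 higher (median 0.31, camera adjusted p = 0.00459, adjusted p = 0.242 with an estimated correlation). The adrenal gene Cyp11a1 read 20.1, 687.6 and 287 in the arrays labelled 1-month Aprt KO 1, 2 and 3, against 10.8 to 98.8 in controls, and adrenal Star 13.8, 628.4 and 305.9 against 13.7 to 60.1. Skeletal muscle Acta1 read 471.6, 7.1 and 3978 in those arrays against 2.2 to 12, and the fat hormone Adipoq 771, 1550 and 1710 against 305.6 to 725.6. At 7 days Cyp11a1 was high in controls 1, 2 and 6 (533.8, 445.2 and 441.5) and in the array labelled 7-day Aprt KO 1 (465.5), and Acta1 in pair 4 (1842 and 1662). With adrenal and muscle scores as covariates, chosen after the values were seen, the 17 genes higher at 1 month had a median log2 fold change of 0.99, against 0.96 without the scores, the median SE went from 0.169 to 0.225, and 2 of them were called.

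In all, limma called 18 of 5744 genes at 1 month, 17 higher and 1 lower, against 79 with the litter pair as a block, 72 higher and 7 lower, and 1 with only the 6 arrays of that age. The count was 7, 10 and 6 without the arrays labelled 1-month Aprt KO 1, 2 and 3, and 7, 4 and 9 without 1-month controls 1, 2 and 3. It was 10, 11, 11, 7, 4 and 5 without pairs 2, 5, 6, 7, 8 and 9. Lcn2 kept its call without any 1 array and lost it in 5 of 48 alternatives, among them without pair 8 or 9 (limma adjusted p 0.0653 and 0.0769). With the mean over its 2 probe sets its log2 fold change was 0.81, against 1.62, and no longer passed, and with only the arrays of that age its limma adjusted p was 0.483. Col1a1 lost it without the array labelled 1-month Aprt KO 1 (0.0585), control 1 (0.0576) or control 2 (0.0547), and without pairs 7, 8 and 9 (0.0574, 0.0981 and 0.0769), by limma adjusted p. Of 48 alternatives Col1a1 lost its call in 8, Krt19 in 6, Col1a2 in 7, Tcf21 in 8, Col3a1 in 9, Lum in 14, Cfi in 15, Postn and Smoc2 in 18, S100a6 in 30 and Serping1 in 34, and Aard in 21 of 47.

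Several lists called at 7 days or with age did not pass at 1 month. Proximal tubule markers had a median of -0.04 and a mean of 0.02 (camera adjusted p = 0.561, 18 of 46 higher), loop of Henle markers 0.02 and 0.06 (0.561, 9 of 17), and Egf and Umod read -0.04 and -0.01. Cell cycle genes read -0.03 (camera adjusted p = 0.0901, 19 of 49 higher), immediate early genes -0.09 (0.561, 11 of 27) and oxidative stress genes 0.03 (0.163, 18 of 33). Fatty acid oxidation had a median of -0.05 and a mean of 0.02 (camera adjusted p = 0.583, 15 of 34 higher), and purine genes -0.04 and 0.01 (0.508, 9 of 23).

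The genotype effects at 7 days and 1 month were compared through the interaction, in which limma called 23 genes, 8 with a more positive effect at 1 month and 15 with a more negative one. Sprr2f, so high at 7 days, had a 1-month signal of 60.2 ± 36.5 in controls and 51.7 ± 41.9 in arrays labelled Aprt KO (SD, n = 3). Its interaction was -5.37 (SE 0.44, limma adjusted p = 3.20e-06). Il1rn (-2.47, SE 0.45), Bcl3 (-2.41, SE 0.25), Fos (-2.37, SE 0.37) and Egr2 (-2.24, SE 0.35) also had the larger effect at 7 days, with limma adjusted p from 4.29e-05 to 0.0141. Aldh1a3 (1.70, SE 0.35), the cell cycle inhibitor Cdkn1c (1.301, SE 0.20), the proteoglycans Lum (1.11, SE 0.20) and Dcn (1.04, SE 0.19), and Tcf21 (1.07, SE 0.21) went the other way, with limma adjusted p from 0.00409 to 0.0323. Cdkn1c stood at 6649 in 7-day controls and 3829 in the arrays labelled Aprt KO, and at 682 and 968 at 1 month. Clu, at 0.37 (SE 0.20) at 1 month, was also called (-1.37, SE 0.25, limma adjusted p = 0.0141). Sprr2f kept its interaction call in all 46 alternatives, Bcl3 lost it in 1 of 46, Fos and Egr2 in 4 of 46 and Il1rn in 11 of 46. Cdkn1c lost it in 2 of 47, Lum in 9, Dcn and Tcf21 in 11 and Aldh1a3 in 21.

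By list, the interaction passed for 16 of 29, 10 upward and 6 downward, 7 of them with an estimated correlation (camera adjusted p from 0.0158 to 0.027). Immediate early genes (median -0.50, 4 of 27 higher, camera adjusted p = 2.81e-16), myeloid markers (median -0.64, 2 of 22 higher, 1.54e-14), complement (median -0.46, 3 of 15 higher, 2.65e-09) and cytokines (median -0.76, 3 of 10 higher, 1.64e-05) rose more at 7 days. Adjusted over the list alone, the interaction was below 0 for 10 immediate early genes and above 0 for 1, below for 10 myeloid genes and above for 2, below for 5 complement genes, and below for 6 cytokines and above for 1. These are differences between the effects at the ages, not falls in signal. The androgen list was lower at 1 month (median -0.26, 2 of 15 higher, camera adjusted p = 3.18e-05). Endothelial markers (median 0.38, 15 of 18 higher, camera adjusted p = 4.47e-05) and urothelium (median 0.58, 5 of 6 higher, 0.00234) were higher. Other-tissue markers moved the same way (median 0.56, 13 of 16 higher, camera adjusted p = 0.000199, adjusted p = 0.0892 with an estimated correlation). Tubular injury genes moved down (median -0.25, 2 of 18 higher, camera adjusted p = 9.32e-07, adjusted p = 0.0661 with an estimated correlation). Matrix genes moved up (median 0.10, 31 of 43 higher, camera adjusted p = 0.00606, adjusted p = 0.164 with an estimated correlation). Proximal tubule genes passed only with the litter pair as a block (camera adjusted p = 0.0769, and 0.0126 with the block, 29 of 46 higher, median 0.10). With the litter pair as a block 93 genes were called, 55 with a more positive effect at 1 month and 38 with a more negative one. That turned the balance of 8 and 15 in the main fit. The number of called genes was 37 without 7-day control 3. It was 8 and 12 without the arrays labelled 1-month Aprt KO 1 and 3, 8 and 15 without 1-month controls 1 and 3, and 11, 15 and 14 without pairs 2, 7 and 9.

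Among genes called higher, Cfi, Krt19, Lcn2, Lsp1, Penk, S100a6 and Serping1 were shared by the ages, 7 against 0.432 for independent sets (Fisher's exact test, one-sided, p = 9.33e-08). The test takes genes as independent, and both sets come from 1 fit with the same spread for a gene at both ages. Its p is therefore not a measure of agreement between mice. Lsp1 and Penk were named here after their values were seen. Of the 185 genes called at 7 days 136 had the same sign at 1 month, and 13 of the 18 called at 1 month had the same sign at 7 days. The share over all genes was not worked out. In the direction of the call, the median log2 fold change of the 7-day calls was 0.774 at 7 days and 0.166 at 1 month. That of the 1-month calls was 0.972 at 1 month and 0.388 at 7 days.

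The postnatal change in control kidney was large, with limma calling 2348 genes, 851 higher and 1497 lower at 1 month. The balance depended on the scaling, with 1227 higher and 1044 lower at equal array medians and 949 and 1148 after quantile normalization. Dnase1 rose most, from a signal of 80.3 to 13730 (7.01, SE 0.30), then the methyltransferase Inmt (4.98, SE 0.27), the cytochrome Cyp2e1 (4.90, SE 0.20), uroguanylin Guca2b (4.80, SE 0.27) and Akr1c21 (4.69, SE 0.30). The falls were led by the histamine-forming enzyme Hdc and proenkephalin Penk (-4.41, SE 0.17). Hdc fell from 1478 to 10.4 (-5.00, SE 0.44), below the pseudocount of 29, and its value ranged from -6.78 to -3.47 over the alternatives, so its rank depended on the pseudocount. Next were Nrep (-3.98, SE 0.18), Postn (-3.92, SE 0.16) and thrombospondin Thbs2 (-3.76, SE 0.19). Limma adjusted p ran from 1.67e-12 to 6.96e-08 over these 10 genes. Proximal tubule markers rose in 35 of 46 cases and fell in 1, 36 and 1 adjusted over the list alone (median 1.00, 41 of 46 higher, camera adjusted p = 5.29e-18). Fatty acid oxidation genes rose in 23 of 34 cases and fell in 1, 28 and 1 adjusted over the list alone (median 0.63, 31 of 34 higher, camera adjusted p = 1.63e-10). Androgen responsive genes rose in 10 of 15 cases and fell in 1, 10 and 2 adjusted over the list alone (median 1.61, 13 of 15 higher, camera adjusted p = 9.77e-08). Matrix genes fell in 39 of 43 cases and rose in 1, 41 and 1 adjusted over the list alone (median -1.53, 1 of 43 higher, camera adjusted p = 2.39e-19). Cell cycle genes fell in 44 of 49 cases, 45 adjusted over the list alone (median -1.32, 1 of 49 higher, camera adjusted p = 3.90e-16). Nephron progenitor genes fell in 20 of 33 cases and rose in 1, 21 and 1 adjusted over the list alone (median -0.90, 5 of 33 higher, camera adjusted p = 1.25e-06), and endothelial markers in 12 of 18, 13 adjusted over the list alone (median -0.80, 3 of 18 higher, camera adjusted p = 0.000488). These 7 lists, of 13 called with age, held with an estimated correlation. Their camera adjusted p was larger, from 0.00167 for matrix genes to 0.0265 for cell cycle genes. The other called lists were lost, among them loop of Henle markers (camera adjusted p = 0.0569) and tubular injury genes (0.164). Without 1-month control 1 the count was 1431 genes.

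Set against this change, the 17 genes higher at 1 month in the arrays labelled Aprt KO, Col1a1, Lcn2 and Tcf21 among them, all fell with age in controls (median log2 fold change -2.41). Across 5744 genes, which are not independent replicates, the 1-month genotype effect correlated with the age change at r = -0.42 (Spearman's rho -0.43). Simulated KO groups without a genotype effect, set against the same controls, gave a mean of -0.11 (-0.23 to 0.03), and the covariance was -0.0731 against -0.0174. At 7 days r was -0.11 (rho -0.11), against a simulated mean of 0.09 (-0.04 to 0.24), with a covariance of -0.0215 against 0.0101. With the 7-day controls split so that the comparisons shared no control but still shared litters, r was -0.165 on average over 20 splits. With the pairs split so that no mouse or litter was shared, chosen after the values were seen, it was -0.134 on average (-0.185 to -0.101 over 20 splits).

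**Figure D3:**
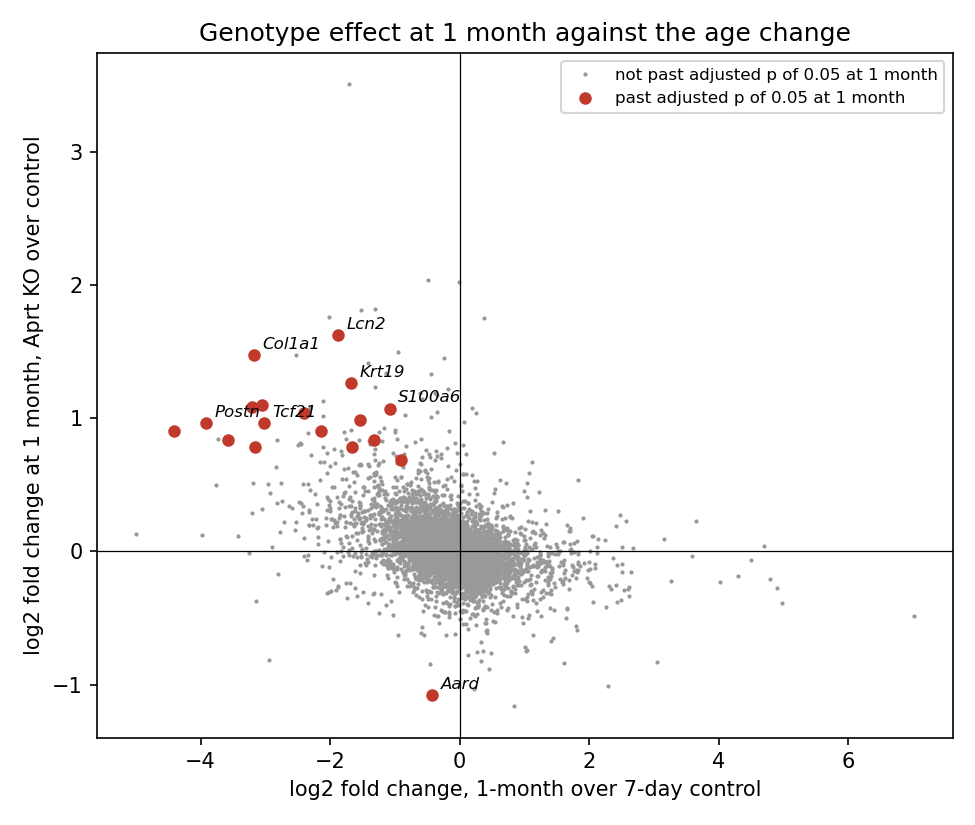
Genotype effect at 1 month against the age change in controls, both as log2 fold changes, with 1 point per gene and genes called at 1 month in red. All 17 red points above 0 lie at negative age changes, with a median of -2.41.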

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

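Of the tests below, the expression score for wrong genotype labels, the gap and the littermate correlation of the Aprt signal and both comparisons of spread between the ages were chosen only after the results they address were seen.

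Single arrays stood far from the rest of their group in 14 of 144 sets of 1 gene and 1 group of 6 arrays, where chance flags about 1 in 20 groups, or 7.2 sets. The measure is the gap to the nearest other array over the whole range, set against Dixon's 95% critical value. The 7-day control 3 was high for Cd74 (0.656; signal 5370.5 against 1019.2 to 1813.2 in the other controls), Ctss (0.656; 844.7 against 146.3 to 275.5), H2-Aa (0.758; 3162.8 against 198.8 to 403.1) and Lyz2 (0.628; 617.7 against 120.5 to 228.7). The 7-day control 1 was low for Aldh1a3 (0.793; 450.3 against 871.4 to 1032.9), Egr2 (0.638; 34 against 82.2 to 124.5) and Gsta4 (0.692; 382.5 against 601.7 to 733.6). The array labelled 7-day Aprt KO 4 was low for Clu (0.681; 3182.9 against 5074.7 to 6313.9), Kap (0.74; 5675.3 against 12801 to 17015.9) and Miox (0.648; 3810.6 against 6261.6 to 8200.1), and high for Aprt (0.756; 135.4 against 41.9 to 58.1). That array and its littermate, 7-day control 4, had a compressed range of bright signals, with a highest signal of 10167.3 and 10766.9 against 25717.7 to 51453.3 on the other arrays. On principal component 3 they stood at -23.7 and -20.24, against -6.12 to 9.87, which bears on readings of bright genes such as Kap on that array. The array labelled 7-day Aprt KO 3 was low for Cd74 (0.729; 2395.2 against 4067.6 to 4952.3) and high for Mep1b (0.73; 592.1 against 398.3 to 443.6), and the array labelled 7-day Aprt KO 1 was high for Fos (0.708; 690.5 against 350 to 428.1).

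The genotype effect differed between the ages for 23 genes by limma's interaction test. The named ones were Sprr2f (-5.37), Il1rn (-2.465), Bcl3 (-2.41), Fos (-2.366) and Egr2 (-2.235), with the larger rise at 7 days, and Aldh1a3 (1.705), Cdkn1c (1.301), Lum (1.107), Tcf21 (1.07) and Dcn (1.041), with the more positive effect at 1 month. Among 693 probe sets without a single gene symbol, which the comparisons do not use, limma called 11 at 7 days, 10 higher and 1 lower, and 0 at 1 month.

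By the midpoints between group medians, the Aprt signal goes against the label in 4 arrays. Wrong labels or the noise of a dim probe set may lie behind it. In the array labelled 1-month Aprt KO 1 the signal still lay below all 1-month controls (86.5 against 103.9 to 109.5). A score of the 50 genes with the smallest genotype p, fitted without the array's own pair, placed 3 of the 3 seven-day arrays and their littermates on the side of their labelled group, which wrong labels forbid; the array labelled 1-month Aprt KO 1 stood at 0.948, with the control mean at 0 and the Aprt KO mean at 1, but its control littermate stood past the midpoint too, at 0.568, so a wrong label is left open there. The within-group SD of this probe set, 0.42, stood at percentile 62.2 of the 500 probe sets nearest in mean signal, whose median SD was 0.376, and the correlation of its log2 signal between 7-day littermates, 0.217, at percentile 39.6. No 7-day array lay between 66.3 and 135.4, with pairs 1 and 2 below and pair 4 above, and this gap, 0.596 of the log2 range, stood at percentile 98.6 of those probe sets, so noise is left open. The sample labels do not describe the KO allele. Genotyping the same mice for it would decide whether the labels are right, and no biological explanation was tested.

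More genes were called at 7 days (185) than at 1 month (18), which may come from the number of arrays, from a larger spread at 1 month or from a larger effect at 7 days. With 3 of the 6 seven-day pairs and all 1-month arrays in the fit, the 7-day count was the higher one in 20 of 20 subsets (20 to 114 against 1 to 12), so the number of arrays is excluded as the whole cause. The typical within-group SD was 0.243 at each age, a ratio of 1 with jackknife bounds of 0.371 to 1.629 that decides nothing. Those fits use 1 spread per gene for both ages, so their median SE is the same at both by construction and does not compare the spreads. Spread adds to the size of estimates, yet more genes were over 2-fold at 7 days in 20 of 20 subsets (55 to 94 against 38). A larger spread at 1 month is therefore excluded as the whole cause. A larger effect at 7 days is the biological alternative and stays a hypothesis, and more 1-month litters would test it.

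Other splits of the arrays gave fewer calls by limma than the labelled groups. At 7 days 1 of 100 splits, the labelled one, called as many as 185 genes; the highest other called 28, and among the 32 splits that part all pairs the highest other called 20. At 1 month the labelled split called 18 genes and the highest other 14, and 1 of 10 splits reached 18; 10 splits are too few for a share under 0.05. Among the 4 one-month splits that part all pairs, the 3 others called 0 genes by limma, with 81 to 137 at an unadjusted p under 0.05 against 265 for the labelled split. For the interaction 1 of 100 draws reached 23, with 19 the highest other. These draws also break up the genotype effect within each age, so they do not test whether the effects at the ages are equal. For age, in controls alone, 1 of 84 splits reached 1884 genes, with 629 the highest other.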

How the results depend on the processing

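Of the alternatives below, those without the 4 arrays whose Aprt signal goes against the label, those with adrenal and muscle scores and the correlations with no shared mouse or litter were chosen only after the results were seen. The arrays number 3 to 6 in a group, which limits precision, and dim genes such as Aprt lie close to the background signal. No call of a named gene reversed, and no age call of a named gene changed. Over all alternatives the 7-day results of named genes stayed on their side of the threshold in 3165 cases, lost it in 150 and gained it in 71; at 1 month these numbers were 2713, 193 and 57, and for the interaction 391, 74 and 0. Beyond the cases given with the results, the litter pair as a block changed the call of no list and of no gene whose genotype p is printed.

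At 7 days limma called 185 genes, and 110 to 208 with an array or pair left out; 500 with the litter pair as a fixed block, 522 with it as a random block and 97 without the 4 arrays whose Aprt signal goes against the label. At 1 month the 18 calls became 28 with a pseudocount of 1, 7 with a pseudocount at the 40th percentile, 10 with the mean over the probe sets of a gene, 79 and 117 with the fixed and random block, 1 with only the arrays of that age, 267 with array weights, 3 without the 4 arrays (109 with the random block too), 8 with the adrenal score and 2 with adrenal and muscle scores. With an array or pair left out they numbered 4 to 21. Genes whose 1-month groups do not overlap numbered 353, against 574.4, or 10% of all genes, if all arrays were exchangeable. Littermates deviated together (correlations 0.539 to 0.602 at 1 month) and every pair is split between the groups, so that reference is not the chance value here. At 7 days 152 genes (2.65%) did not overlap, against 12.4 (0.216%) by the same reference. The age calls, 851 higher and 1497 lower, were 1227 and 1044 with equal array medians; the cause was not tested. The 23 interaction calls became 93 and 142 with the fixed and random block, 154 with array weights, 7 without the 4 arrays (60 with the random block too) and 2 with both scores, and 8 to 37 with an array or pair left out. With an array or pair left out the age count ranged from 1431 to 2367. Fewer arrays explain part of the lower counts by construction; for the other shifts the cause was not tested.

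The Aprt difference at 7 days, -0.58 with a limma adjusted p of 0.0672, passed the threshold with quantile normalization (-0.5992, 0.0336), equal medians (-0.5969, 0.043), the fixed block (-0.5817, 0.0338), the random block (-0.5817, 0.0187), array weights (-0.6356, 0.0272), the adrenal score (-0.7106, 0.0171) and both scores (-0.681, 0.0236); the cause was not tested. With an array or pair left out it ranged from -0.7413 to -0.4456 at 7 days and from -0.6836 to -0.4596 at 1 month.

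The number of called lists at 1 month, 14, was 9 with array weights and 9 with both scores, and 9 to 14 with an array or pair left out; at 7 days it was 14 to 17, for the interaction 14 to 19 and for age 13 to 14. Reversed were the other-tissue list at 1 month with the adrenal score (camera adjusted p = 0.963), the antigen presentation list in the interaction with both scores (0.0465) and the interferon list in the interaction without 7-day control 3 (0.02) or pair 3 (0.01405), where leaving out other arrays or pairs gave up to 0.972; the cause was not tested. The correlation with the age change was -0.165 at 7 days with split controls, and with no shared mouse or litter -0.134 at 7 days and -0.25 at 1 month, and with a pair left out -0.119 to -0.074 and -0.45 to -0.398.

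Lists were not run under the random block, other eBayes settings, uncollapsed probe sets and non-overlap, nor the interaction under non-overlap or the age comparison under the fixed block.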

Other observations

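Of the tests below, the correlations without a shared mouse or litter and the cell cycle test were chosen only after the correlation with age was seen, while the tissue covariates were predicted beforehand from marker genes picked after their values were seen.

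The genes called at 7 days and 1 month were set beside the change with age in controls. Of the 146 genes higher at 7 days in arrays labelled Aprt KO, 16 rose and 61 fell with age in controls (median -0.37), and of the 39 lower genes 18 rose and 9 fell (median 0.32). Of all 5744 genes 851 rose and 1497 fell (median -0.11), or 1227 and 1044 with equal array medians, and the 7-day effect and the age change share the 7-day controls. Lcn2 and Krt19 fell with age (-1.88 and -1.68), Clu read 0.01, and Egf and Klk1, lower at 7 days, rose with age (3.58 and 2.57). Of the 17 genes higher at 1 month, 0 rose and 17 fell with age.

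The genes higher at 1 month that fall with age may reflect slower maturation of the kidney, adrenal and muscle tissue carried into the samples, or the controls that both comparisons share. With adrenal and muscle scores as covariates the median log2 fold change of the 17 genes was 0.987, against 0.961 without them. The median SE was 0.225 against 0.169, and 2 of the 17 genes were still called. By the median log2 fold change, these scores did not account for the rise of the 17 genes. The median of the matrix list went from 0.484 to 0.389 with both scores. The fit takes 1 log2 slope per gene over both ages. Col1a1 in controls read 5126.9 to 9363.5 at 7 days and 604.7 to 835.4 at 1 month, so added tissue could shift the ages unequally. Carried-over tissue is therefore left open, and the scores do not cover fat or urothelium. The highest of 3 correlations from arrays that share no mouse or litter was -0.185. Shared controls cannot produce these correlations, but no chance range was worked out for them. For slower maturation, the same measure outside the matrix list and the called genes was -0.144, the side it predicts. That measure kept 5690 of 5744 genes, again without a chance range. It does not tell slower maturation from other causes that raise genes which fall with age. Proximal tubule, loop of Henle (lost with an estimated correlation) and fatty acid oxidation lists rose with age (medians 1.00, 0.76 and 0.63). They did not pass at 1 month (medians -0.04, 0.02 and -0.05). Nephron progenitor (lost with an estimated correlation), endothelial and androgen lists moved against their age change at 1 month (medians 0.12, 0.25 and -0.23). No predicted value was worked out for these lists. Cell cycle genes read -0.031 in median, against 0.171 predicted by slower maturation, with pair medians from -0.221 to 0.111, which leaves that part open; staining kidneys of more 1-month litters for collagen and dividing cells would test it.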
